A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

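Total RNA from 4 wild-type and 4 zfs1-deficient cultures of fission yeast was measured on 8 arrays. Per the labels' protocols, cells were grown at 30 °C to an optical density of 1, and 1 µg of total RNA was amplified into biotin-labelled cRNA with a 3′ amplification kit. Of this, 5 µg was fragmented and hybridised for 16 h to an Affymetrix array, and signals were obtained with the GeneChip Operating Software. The labels name an array type of a nematode, whereas the organism is fission yeast and the probe sets of the value table are paired with fission yeast genes in the probe table used here, so the array type stays unsettled. The labels give 4 cultures per strain, numbered 1 to 4 in each.

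The deposited values are read as log10 signal. The base is inferred from the values, since every array's median lay between 2.890 and 2.901 and its maximum between 3.94 and 3.99, and no source used here states it. How the authors scaled and summarised the probes before they deposited the log10 values is not given in the sources used here. No direction had to be settled, since each array holds 1 RNA sample. Values were multiplied into log2 and otherwise used as deposited, because the array medians differed by less than 0.3 on the log2 scale. If the base were another, all log2 values, differences and folds would scale by 1 factor, and the p-values of limma and camera without an offset would not change, but whatever rests on a fixed log2 value would: the counts at 2-fold, the offsets, the level set for dim signals and the bounds set on list medians.

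The table held 5011 probe sets. The 17 reporter controls were left out of the test and served as the measure of background. What these controls match is not given in the sources used here. Of the 4994 others, 228 values (0.571%) were missing, in 80 probe sets with a median signal of 3.44 against 9.62 for all, and 25 probe sets with fewer than 2 values in a strain were not tested. Where all 4 arrays of a strain lay at or below the brightest reporter control of their array, the fold is given as a bound, set per array from the higher of that control and the probe set's own signal. Gene names came from a probe table and were updated by gene identifier through a gene table of assembly ASM294v3: 2916 probe sets had 1 symbol, 20 had several and 2058 none, 2913 were found in the gene table and 110 symbols changed. Only probe sets with 1 symbol were named. For each of 2882 genes the probe set with the highest mean over the 8 arrays was used, and systematic names are those of the gene table. The build of the array's design is not given, so no coordinates are printed. The probe set listed for the acid phosphatase gene of the phosphate list was matched by its identifier to a non-coding RNA at that locus, and it is counted in the list but not named.

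The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 2-sided), with Benjamini-Hochberg adjustment over the 4969 tested probe sets and a threshold of 0.05. Gene lists were compared with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 21 lists of at least 3 members, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, gave an unadjusted p under 0.05 for 7 of the 21 and an adjusted p under 0.05 for 4, those of metal supply, mRNA decay, nutritional markers and stress. The camera test used the 2864 genes with a value on every array. Of 24 lists, those of the deleted gene, the reported targets and the Tf2 retrotransposons had too few measured members for it. Figures were drawn with matplotlib 3.10.9.

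The test, the lists, the rule for named genes and the first group of alternative settings given at the end were fixed before the data were examined. The rule named zfs1, every measured nutritional marker and reported target, the 15 largest increases and the 10 largest decreases among called genes whose arrays did not overlap between strains, and up to 4 members with the smallest adjusted p of each list with a called member. Apart from these 44 genes, list members given with their values as points of reference, and the genes of the added lists and of the replicate 4 comparison, were chosen after their values were seen. The planned search for the AU-rich element bound by this protein family in 3′ untranslated regions needs a genome and was not analysed here.

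The labels do not say that a shared number marks a shared day or batch. Across probe sets, the deviations of same-numbered arrays from their strain means correlated at 0.37 for number 1, 0.33 for 2, 0.26 for 3 and 0.70 for 4. All 4 exceeded the 0.1 set as the rule, so the numbers were taken to pair the cultures, and values with the replicate number as a block stand beside the results they change. Some arrays of unlike number exceeded it too: wild-type 1 with zfs1-deficient 3 at 0.41, and wild-type 3 with zfs1-deficient 1 at 0.25. The deviations thus do not tell the pairing of numbers 1 and 3 from the crossed one, and the block rests on the labels' numbers there. P-values measure the spread between these cultures.

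The test was tried on simulated data for 4914 probe sets and 8 arrays with 67, 67 and 66 changed probe sets. With no replicate effect and no block it recovered 35.8% at a log2 change of 0.5, 74.6% at 1 and 97.0% at 2, with 2.82% false calls. With simulated replicate effects, it recovered 25.4%, 80.6% and 95.5% without the block, with 2.19% false calls, and 62.7%, 86.6% and 93.9% with it, with 3.57% false calls. Among 21 simulated lists of 20 genes, the 1 list shifted by 0.4 was called and 0 of the others. The simulated genes varied independently, whereas estimated correlations within the measured lists reached 0.43, for flocculation and adhesins. The simulation therefore does not show how often lists of correlated genes are called falsely.

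The alternatives were quantile normalisation, centring on array medians, leaving out the dimmest 25% of probe sets, no variance trend, array weights, the replicate block, 1 probe set per gene, leaving out probe sets open to cross-hybridisation, an adjusted p of 0.01, testing all probe sets of the table, and leaving out each array. Chosen after seeing the data were replicate 4 as a batch term, the strains without both replicate 4 or both replicate 2 cultures, the mean of zfs1-deficient replicates 1 and 3 as 1 sample, and offsets of 16 and 64 added to the back-transformed signal.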

Results

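Messenger RNA levels were measured in the fission yeast Schizosaccharomyces pombe, in a wild-type strain and in a strain deficient in zfs1. The series names zfs1 as the gene of a protein that binds and destabilises mRNA, and the protein belongs to the tandem CCCH zinc finger family. Each strain was grown at 30 °C in supplemented Edinburgh minimal medium, and 4 cultures per strain were each hybridised to 1 Affymetrix array, giving 8 arrays. Of 4994 yeast probe sets, 4969 could be tested, and the array medians lay between 9.61 and 9.64 on the log2 scale. Signals are on that scale, differences are zfs1-deficient minus wild type, and the number of arrays limits their precision.

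The zfs1 transcript (SPBC1718.07C) was present in every wild-type culture and at background in every zfs1-deficient culture. Its signal was 10.51 ± 0.10 (SD, n = 4) in wild type and 4.14 ± 0.45 (SD, n = 4) in the deficient strain, a difference of -6.37 ± 0.21 (SE; limma, Benjamini-Hochberg adjusted p = 5.23e-07). The 4 deficient arrays lay within the range of the reporter control probe sets, read here as background, so the fall was at least 31.8-fold. No array went against its label. Among 7 nutritional marker genes, leu1 (SPBC1A4.02C, leucine synthesis) fell by 0.30 ± 0.05 (SE, n = 4 per strain; adjusted p = 0.0107), and ura4 (SPCC330.05C, uracil synthesis) differed by -0.11 ± 0.05 (adjusted p = 0.249). In this marker list 0 rose and 1 fell, or 2 fell when adjusted over the list alone, and the median was -0.30 (camera adjusted p = 0.00135; adjusted p = 0.320 with an estimated correlation). With the replicate number as a block, 4 of the 7 fell, among them ade6, his3 and lys1.

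Apart from zfs1 itself, the largest differences between the strains among named genes were increases in the deficient strain. The question of this comparison was which steady-state transcripts differ when the destabilising protein is missing. lsd90 (SPBC16E9.16C, a gene of the stress list described later) rose from 6.85 ± 0.38 to 10.07 ± 0.82 (SD, n = 4), a difference of 3.22 ± 0.37 (SE; adjusted p = 0.00192) or 9.33-fold. inv1 (SPCC191.11), which encodes the sucrose-splitting enzyme invertase, rose by 2.42 ± 0.45 (SE; adjusted p = 0.0165). pfl8 (SPAC1F8.06), a cell surface glycoprotein of the flocculin family, rose by 2.06 ± 0.35 (SE; adjusted p = 0.0107). Of the 4969 probe sets, 177 were higher and 110 lower without zfs1, and 44 and 21 of these differed by at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). With the replicate number as a block, 563 were higher and 638 lower, so that decreases became the more numerous, and all 287 of the unblocked calls were among them. The 21 decreases of at least 2-fold became 32 with the block, 13 without wild-type replicate 1 and 9 without zfs1-deficient replicate 1 or 3. With array weights 761 were higher and 756 lower, 79 and 55 of them by at least 2-fold, and without the dimmest 25% of probe sets 25 and 6 reached 2-fold. The weights were largest for zfs1-deficient replicates 1 and 3 (6.55 and 5.50), the arrays most alike. They were smallest for replicate 4 of wild type (0.23) and of the deficient strain (0.18). Leaving out 1 array lowered the count from 287 to 127 without wild-type replicate 1, 150 without wild-type replicate 2, 151 without wild-type replicate 3, 117 without zfs1-deficient replicate 1, 182 without zfs1-deficient replicate 2 and 103 without zfs1-deficient replicate 3.

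arz1 (SPCC1494.03), an armadillo repeat protein, rose from 8.99 ± 0.07 to 10.97 ± 0.17 (SD, n = 4), a difference of 1.98 ± 0.10 (SE; adjusted p = 1.82e-05) or 3.94-fold, with the smallest adjusted p among the named increases. The study itself picked arz1 on these samples, so its rise is not independent evidence. cbf12 (SPCC1223.13), a transcription factor of the CSL family tied to cell adhesion in later work, was 0.74 ± 0.23 higher (SE; adjusted p = 0.108), and passed with the replicate number as a block (adjusted p = 0.00138). Of the 2 measured genes of this target list 1 rose, or 2 when adjusted over the list alone. cbf12 was higher in the deficient strain in 4 of 4 numbered pairs.

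**Figure D1:**
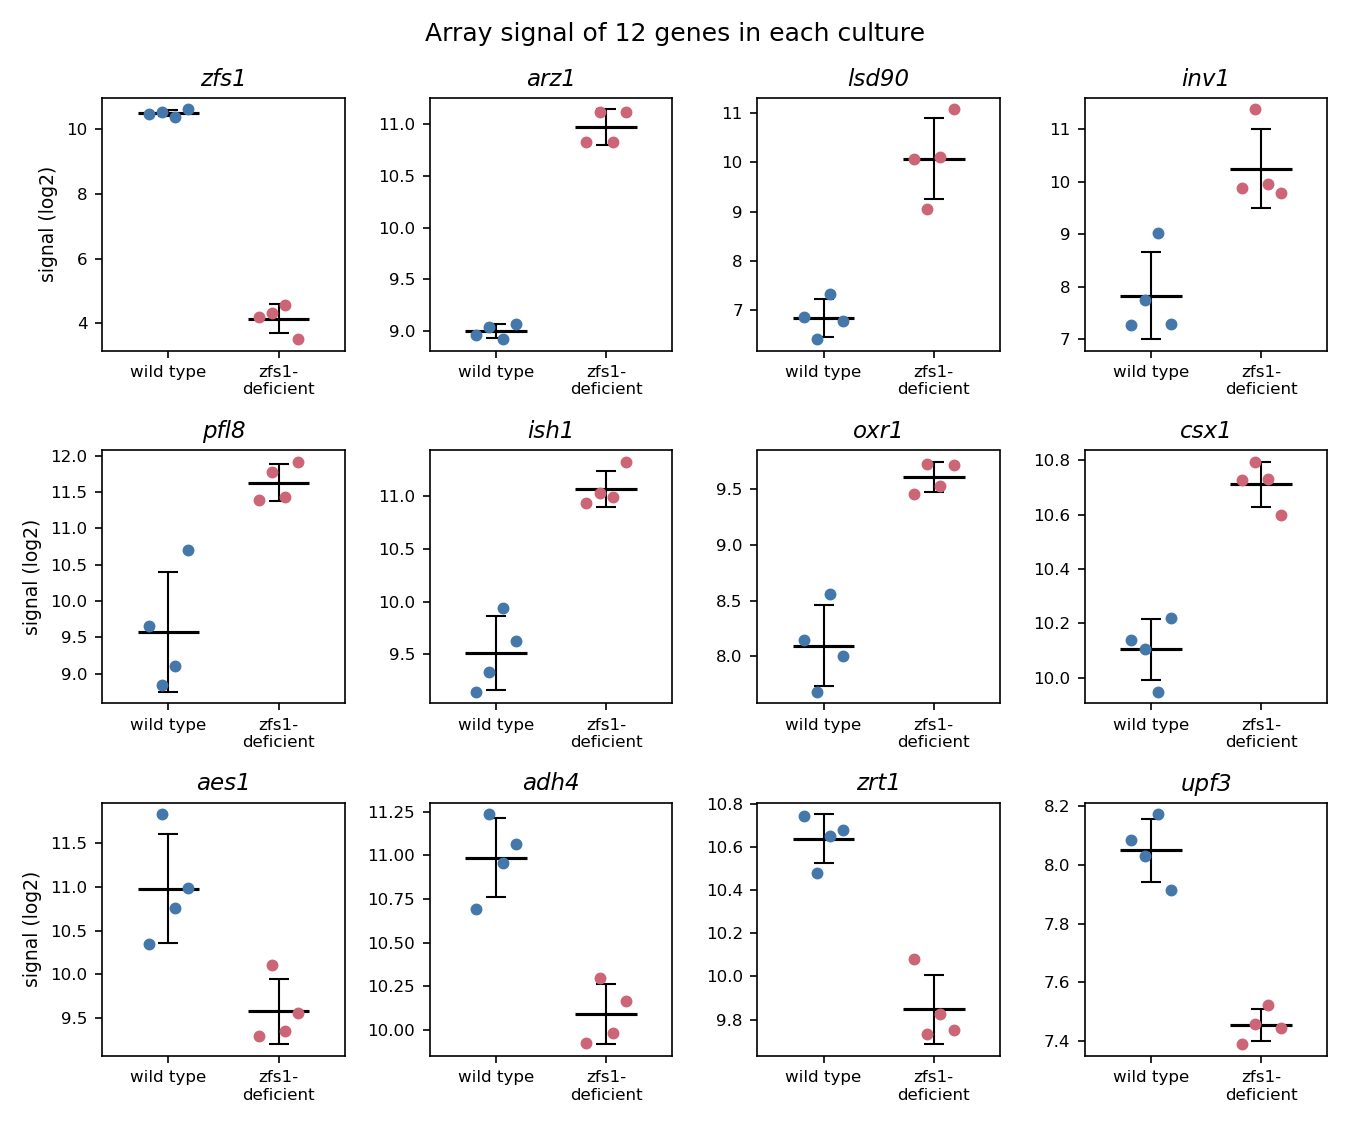
Signal (log2, vertical axes with separate ranges) of 12 genes on each of the 8 arrays, by strain. Points are single cultures, horizontal lines are means and whiskers are SDs (n = 4); zfs1 falls at least 31.8-fold, its 4 zfs1-deficient points being within background, arz1 to csx1 are higher without zfs1 and aes1 to upf3 lower, with no overlap between the strains in any panel.

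Among 2882 genes with 1 name, 87 rose and 41 fell, and with the replicate number as a block 299 rose and 320 fell. Besides the genes above and isp3, 10 of the 15 largest named increases ran from 1.59 to 0.96. isp3 (SPAC1F8.05), a spore wall component, lay within the reporter control range on all 4 wild-type arrays and on 3 of the 4 zfs1-deficient arrays. It passed the test (adjusted p = 0.0498), and the bound by the rule was 1.29-fold, but this rests on signals mostly at background. The brightest reporter control was itself higher in the deficient strain in 4 of 4 numbered pairs, by 0.05 to 1.03, so no smallest rise is established for isp3. spo6 (SPBC1778.04), a regulator of meiotic division, rose by 1.59, mug2 (SPBC106.08C), from a set of genes raised in meiosis, by 1.56, and ish1 (SPBC365.12C), a stress-responsive nuclear envelope protein, by 1.55. oxr1 (SPAC8C9.16C), a TLDc domain protein, rose by 1.51 and rds1 (SPAC343.12), a stress-responsive gene, by 1.47. rgs1 (SPAC22F3.12C), which dampens G protein signalling in the pheromone response, rose by 1.16. tcb2 (SPCP31B10.06), a tricalbin, rose by 1.11, egt1 (SPBC1604.01), of ergothioneine synthesis, by 1.10, ypt4 (SPAC1B3.11C), a Rab GTPase, by 0.97, and mkh1 (SPAC1F3.02C), a MAP kinase kinase kinase of the cell integrity pathway, by 0.96. Adjusted p for these 10 lay between 0.00147 and 0.0270. Each was higher in 4 of 4 numbered pairs, which the rule fixed in advance by requiring arrays that do not overlap. With each array left out in turn, isp3 kept its call in 1 of 8 fits, rds1 in 3, inv1 and spo6 in 6, tcb2 in 7 and the other 10 in all 8. The highest adjusted p in those fits was 0.151 for isp3, 0.0780 for rds1, 0.0560 for inv1, 0.0706 for spo6 and 0.0528 for tcb2.

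Other than that of zfs1, the decreases of named genes were at most 1.41 in size. aes1 (SPBPB21E7.07), an enhancer of RNA-mediated gene silencing, fell by 1.41 ± 0.30 (SE; adjusted p = 0.0290), fip1 (SPAC1F7.07C), an iron permease, fell by 0.99, and adh4 (SPAC5H10.06C), an alcohol dehydrogenase, fell by 0.89. liz1 (SPBC2G2.01C), a pantothenate transporter, fell by 0.86, trm13 (SPAC1805.03C), a tRNA methyltransferase, fell by 0.85, and zrt1 (SPBC16D10.06), a zinc transporter, fell by 0.79. gdh2 (SPCC132.04C), a glutamate dehydrogenase, fell by 0.76, dbr1 (SPAC17A5.02C), the lariat debranching enzyme, fell by 0.68, and alr1 (SPCC965.08C), alanine racemase, fell by 0.68. Their adjusted p lay between 0.00437 and 0.0493. gdh2 missed the threshold when array medians were centred (adjusted p = 0.0533), and fip1 and gdh2 missed it in every fit with 1 array left out (highest adjusted p of 0.118 and 0.128). adh4, zrt1 and dbr1 were called in all 8 such fits, aes1 in 5, liz1 in 3, alr1 in 2 and trm13 in 1.

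Probe sets without a single gene name, 2070 of the 4969 tested, held most changes of at least 2-fold. These were 31 of the 44 higher and 19 of the 21 lower. 1778738_at rose from 7.46 ± 0.54 to 10.76 ± 0.13 (SD, n = 4), a difference of 3.30 ± 0.23 (SE; adjusted p = 1.11e-04), and 1773509_at rose by 3.21 ± 0.33 (SE; adjusted p = 0.00124). 1773163_at fell by 2.23 ± 0.48 (SE; adjusted p = 0.0313) and 1771259_at fell by 2.21 ± 0.34 (SE; adjusted p = 0.00779). In all, 159 of the 287 changed probe sets had no single gene name, and 580 of 1201 with the replicate number as a block.

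The core environmental stress response, a gene set raised in fission yeast by many kinds of stress, was called higher without zfs1 as a list by camera (adjusted p = 1.26e-06; adjusted p = 0.320 with an estimated correlation, so the call did not hold there). Of its 23 measured genes 8 rose and 0 fell, or 11 rose when adjusted over the list alone, and the median difference was 0.41. Besides lsd90, ish1 and rds1, gpx1 (glutathione peroxidase) rose by 0.85, psi1 (an Hsp40 chaperone) by 0.61 and gpd1 (glycerol-3-phosphate dehydrogenase) by 0.46. The stress transcription factor gene atf1 differed by -0.05 (adjusted p = 0.880) and the catalase gene ctt1 by 0.62 (adjusted p = 0.212, and 0.0266 with the replicate number as a block). With the replicate number as a block 13 rose. The same list was also higher in the replicate 4 cultures of both strains than in the other cultures (median 0.25, camera adjusted p = 0.0421), and without both of them its strain difference had a median of 0.41 (camera adjusted p = 2.93e-04). The comparison of the replicate 4 cultures, here and below, was chosen after the data were seen and rests on 1 array per strain. Its camera values were obtained only at the preset correlation, where calls between the strains did not hold with an estimated one. Heat shock chaperones as a list were not called (camera adjusted p = 0.733): 1 of 22 rose, psi1, and 1 when adjusted over the list alone, 2 rose and 2 fell with the block, and the median of -0.05 and the mean of 0.03 differed in sign. psi1 kept its call in 6 of the 8 fits with an array left out (highest adjusted p = 0.0545).

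Among genes of meiosis and sporulation 2 of 26 passed the test, and among genes of cell adhesion 1 of 9. The meiotic genes that rose were spo6 and isp3, the latter near background. In that list 4 rose and 1 fell when adjusted over the list alone. The median of the 26 was 0.37 (camera adjusted p = 0.0259; adjusted p = 0.567 with an estimated correlation). The meiotic regulator genes mei4, at 0.74 (adjusted p = 0.163, and 0.0209 with the replicate number as a block), and mei2, at 0.03 (adjusted p = 0.976), did not pass without the block. The meiotic list was no longer called with the dimmest 25% of probe sets left out (median 0.076, adjusted p = 0.722), or without wild-type replicate 4 or zfs1-deficient replicate 1 or 3 (highest adjusted p = 0.0933; median 0.25 without the last). Leaving out the dimmest 25% took spo6 and isp3, the 2 called genes, out of the list. That lost call thus does not tell whether the rise is one of dim signals, and spo6 lay above the reporter controls on every array. The median of the meiotic list was 0.14 with an offset of 64 added to the signal and 0.24 without both replicate 4 cultures, and the reporter controls, the measure of background, had a median 0.59 higher in the deficient strain. Of 9 measured flocculins, adhesins and their regulators 1 rose, pfl8, or 3 when adjusted over the list alone, and the median was 0.45 (camera adjusted p = 0.0384; adjusted p = 0.567 with an estimated correlation). With the block 6 meiotic genes rose and 1 fell, and 4 adhesion genes rose. The adhesion list was lower in the replicate 4 cultures of both strains (median -0.52, camera adjusted p = 0.0421), with 7 genes lower and 1 higher. The higher one was pfl8, by 0.94 (1.50 in wild type and 0.38 in the deficient strain). The call of the adhesion list between the strains was lost with the dimmest 25% left out (median 0.27, adjusted p = 0.173), without zfs1-deficient replicate 1, 2 or 3 or without wild-type replicate 4 (highest adjusted p = 0.153; median 0.30 without the last).

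Mating genes went both ways. Of 17 genes shared by the mating types 1 rose, rgs1, and 1 fell, byr1, the MAP kinase kinase of the pheromone pathway, which fell by 0.55 ± 0.14 (SE, n = 4; adjusted p = 0.0483; called in 1 of the 8 fits with an array left out, highest adjusted p = 0.119). When adjusted over the list alone 2 rose and 1 fell, and with the block 2 rose and 1 fell. Their median was 0.04 (camera adjusted p = 0.682), and ste11, the regulator of sexual development, differed by 0.04 (adjusted p = 0.946). Of 5 measured genes of P cells, sxa1, an aspartic protease of the pheromone system, rose by 0.31 ± 0.05 (SE; adjusted p = 0.0125; 0.0520 without 1 array), 1 when adjusted over the list alone, and with the block 2 rose and 1 fell (camera adjusted p = 0.446; median -0.02 and mean 0.02 differ in sign). Of 7 measured genes of M cells 0 passed in limma, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.924; median -0.11 and mean 0.0023 differ in sign).

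Among genes of metal supply 3 of 19 fell without zfs1, and among genes of sugar uptake and glycolysis 2 of 21 rose. Of the 19 measured genes of iron, copper and zinc supply 0 rose and 3 fell, zrt1, fip1 and adh4, or 4 fell when adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.00187; adjusted p = 0.171 with an estimated correlation), and with the block 1 rose and 5 fell. The estimated correlation of this list was -0.0078, below the preset 0.01. Its unadjusted camera p still went from 3.56e-04 to 0.00815, so correlation between its genes does not account for the weaker result. adh4 is a dehydrogenase gene that responds to zinc supply rather than a transporter. Of 21 measured hexose transport and glycolysis genes 2 rose, inv1 and the hexose transporter gene ght2 (0.61 ± 0.12, SE; adjusted p = 0.0226, and up to 0.0800 with an array left out), and 2 when adjusted over the list alone. The glycolytic genes tpi1, at 0.08 (adjusted p = 0.271), and pgk1, at 0.06 (adjusted p = 0.508), did not pass, and with the block 3 genes of the list rose and 1 fell. The median was 0.07 (camera adjusted p = 0.0187; adjusted p = 0.567 with an estimated correlation). The call of this list was lost under quantile normalisation (median 0.026, adjusted p = 0.109), without wild-type replicate 4 (median 0.043, adjusted p = 0.295) and without zfs1-deficient replicate 2 (median 0.043, adjusted p = 0.0569). The median was 0.10 without wild-type replicate 2 or 3, and the list was lower in the replicate 4 cultures of both strains (median -0.19, camera adjusted p = 0.0421).

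Phosphate and nitrogen starvation genes were not called as lists. Of 4 measured phosphate genes 1 rose, vtc4, which acts in polyphosphate synthesis, by 0.50 ± 0.07 (SE, n = 4; adjusted p = 0.00511). When adjusted over the list alone 1 rose and 2 fell, and with the block 1 rose and 1 fell (median -0.33, camera adjusted p = 0.600). Of 17 nitrogen starvation and amino acid transport genes 0 passed in limma, and 1 was higher and 4 lower at an unadjusted p under 0.05. When adjusted over the list alone 1 rose and 2 fell, and with the block 3 rose and 6 fell (median -0.12, camera adjusted p = 0.412).

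Among genes of ribosomes, histones and septation, hht3 was the 1 gene to pass the test. Of 119 ribosomal protein genes 0 passed in limma, 0 when adjusted over the list alone and 10 at an unadjusted p under 0.05, and with the block 3 rose. Their median was 0.05 (camera adjusted p = 1.02e-05; adjusted p = 0.567 with an estimated correlation), and the call was lost under quantile normalisation, where the median was 0.0019 (adjusted p = 0.618), and the median was 0.032 without wild-type replicate 4. Of 15 ribosome biogenesis genes 0 passed, 0 when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05, with a median of -0.10 (camera adjusted p = 0.0384; adjusted p = 0.567 with an estimated correlation), and 4 fell with the block. That call was lost with array weights (median -0.030, adjusted p = 0.117) and without wild-type replicate 1 or 3 or zfs1-deficient replicate 2 or 4 (highest adjusted p = 0.187). With 1 array left out the median ran from -0.041, without zfs1-deficient replicate 2, to -0.17, without wild-type replicate 4, and was -0.062 without wild-type replicate 1 or 3 and -0.16 without zfs1-deficient replicate 3. Of 11 histone genes 1 rose, the histone H3 gene hht3, by 0.38 ± 0.07 (SE; adjusted p = 0.0167, and up to 0.0638 with an array left out), 1 when adjusted over the list alone and 5 with the block. The histone median was 0.13 (camera adjusted p = 0.0149; adjusted p = 0.320 with an estimated correlation), and the call was lost without zfs1-deficient replicate 4 (adjusted p = 0.0851). Of 31 septation genes 0 passed in limma, 0 when adjusted over the list alone, 3 were higher at an unadjusted p under 0.05 and 4 rose with the block. Their median was 0.18 (camera adjusted p = 0.0187; adjusted p = 0.383 with an estimated correlation), and the call was lost without wild-type replicate 4 (median 0.10, adjusted p = 0.0933) and without zfs1-deficient replicate 2 (median 0.087, adjusted p = 0.0821).

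cig2, a cyclin gene transcribed at the start of S phase, rose by 0.66 ± 0.11 (SE, n = 4; adjusted p = 0.0107). It was 1 of 14 measured targets of the MBF transcription factor to rise, 2 when adjusted over the list alone and 2 with the block. That list was not called (camera adjusted p = 0.462; median -0.01 and mean 0.09 differ in sign), with cdc18 at 0.15 (adjusted p = 0.785) and cdc22 at -0.02 (adjusted p = 0.946). Of 21 sterol synthesis and hypoxia genes 0 passed in limma, 0 when adjusted over the list alone and 3 were lower at an unadjusted p under 0.05. Their median was -0.14 (camera adjusted p = 0.0329; adjusted p = 0.498 with an estimated correlation), and with the block 1 rose and 6 fell, erg11 among the lower ones at -0.26 (blocked adjusted p = 0.00336). The call of the sterol list was lost without wild-type replicate 2 (adjusted p = 0.127) and without zfs1-deficient replicate 4 (median -0.074, adjusted p = 0.118).

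Genes of mRNA decay and of RNA-binding regulators were not called as lists by camera, which sets a list against other genes. The fry test, which does not, gave the decay list a lower balance (unadjusted p = 0.00126, adjusted p = 0.0133 over the 21 lists). upf3, a factor of nonsense-mediated decay, fell by 0.60 ± 0.11 (SE, n = 4; adjusted p = 0.0176, and up to 0.0760 with an array left out), as the 1 of 22 measured decay genes to pass and the 1 when adjusted over the list alone, while 1 rose and 2 fell with the block (median -0.03, camera adjusted p = 0.412). The deadenylase genes ccr4 (0.06) and caf1 (0.01) and the decapping gene dcp2 (-0.03) did not pass. Among 17 RNA-binding regulators 1 rose and 1 fell, or 2 and 1 when adjusted over the list alone. csx1, which stabilises atf1 mRNA in stress, rose by 0.61 ± 0.09 (SE; adjusted p = 0.00660), and upf3 was the decrease (median 0.05, camera adjusted p = 0.600). The median of these regulators changed sign with 1 array left out, from -0.016 without zfs1-deficient replicate 1 to 0.12 without wild-type replicate 1. With the block 2 rose and 2 fell.

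Genes near chromosome ends went both ways. Of 9 measured subtelomeric genes pfl8 and rds1 rose and aes1 fell, 3 rose and 4 fell when adjusted over the list alone, and 3 rose and 2 fell with the block. The list was not called by camera (adjusted p = 0.600), fry gave an unadjusted p = 0.0303 downward (adjusted p = 0.106), and its median of -0.16 and mean of 0.12 differed in sign. Of the 21 lists tested, 11 were called by camera at its preset correlation of 0.01, 0 with an estimated correlation (3 at an unadjusted p under 0.05), and 11 with the replicate number as a block. Of the 11, 5 also had an unadjusted fry p under 0.05, those of nutritional markers, stress, metal supply, histones and septation, and 6 did not. Without wild-type replicate 4, or without zfs1-deficient replicate 2, 7 were called. Tf2 retrotransposon genes had no measured member under 1 name.

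**Figure D2:**
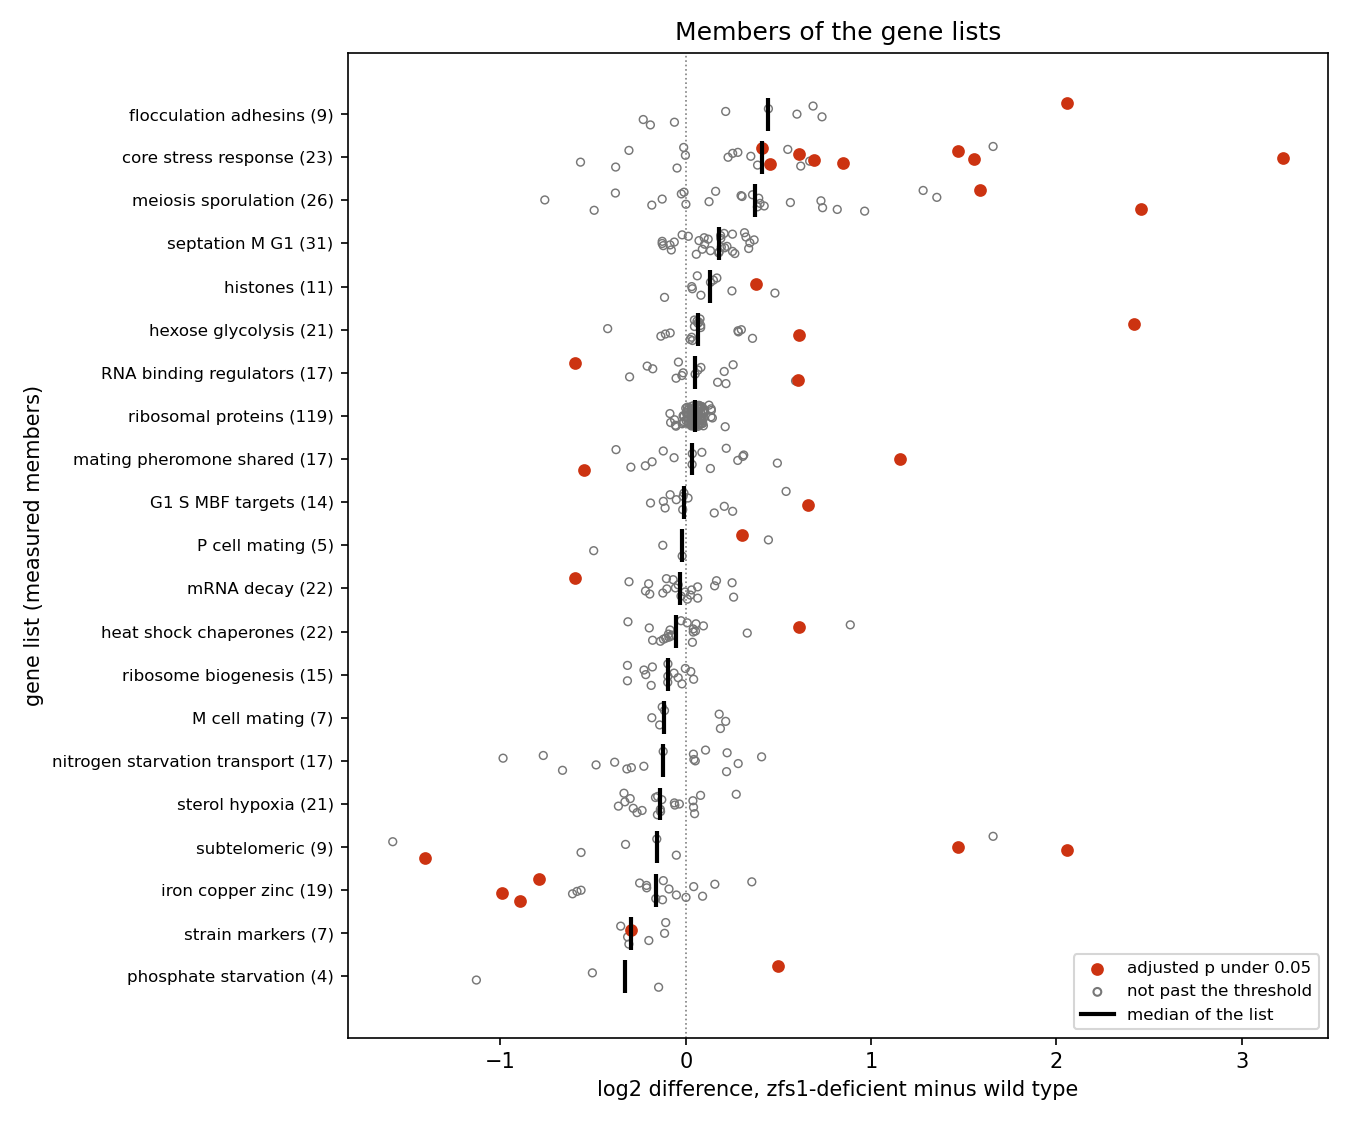
Difference in signal (log2, zfs1-deficient minus wild type, horizontal axis) of each measured member of 21 gene lists, with the number of members in brackets. Filled red points passed adjusted p 0.05 in limma, open grey points did not, and black bars are list medians, which run from -0.33 for phosphate starvation to 0.45 for flocculation and adhesins.

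Within strains, arrays correlated at 0.949 to 0.992 across probe sets, and between strains at 0.929 to 0.966. The replicate 4 cultures of both strains stood apart from the others. In a limma fit with strain as a term, 799 probe sets were higher and 1003 lower in the replicate 4 cultures than in the rest (4914 tested). fbp1, the gluconeogenic enzyme fructose-1,6-bisphosphatase, was 2.85 ± 0.50 higher there (SE; adjusted p = 0.00231), zym1, a metallothionein gene, 1.80 ± 0.29 higher (adjusted p = 0.00162) and the small heat shock gene hsp16 1.42 ± 0.18 higher (adjusted p = 5.13e-04). The fbp1 value averages unlike strains, 1.41 in wild type and 4.29 in the deficient strain, with 1 replicate 4 array each. Without both replicate 4 cultures 609 probe sets differed between the strains, 332 higher and 277 lower, including 274 of the 287. zfs1-deficient replicates 1 and 3 were the most alike of all pairs (r = 0.992), with an SD of their difference of 0.22 against at least 0.32 for other pairs within a strain, and were kept as 2 cultures. With their mean as 1 sample 114 probe sets differed.

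**Figure D3:**
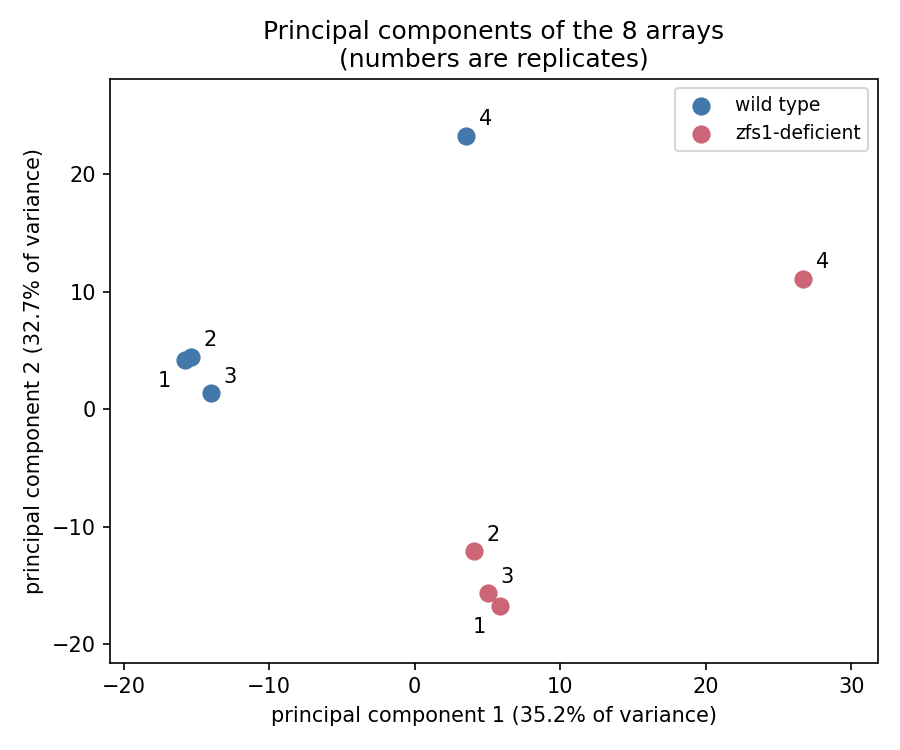
Principal components 1 (35.2% of variance) and 2 (32.7% of variance) of the 8 arrays in arbitrary units, with replicate numbers beside the points. Wild type and zfs1-deficient replicates 1 to 3 lie together within each strain, and replicate 4 of each strain lies apart from them.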

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

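Tests of chance by other splits, of gene length and of the stress list without the replicate 4 cultures were set before their results were seen. The tests of the changed probe sets without the replicate 4 cultures, of dim signals and of nutrient limitation were chosen after the results were seen.

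The first pattern is the number of changed probe sets. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 287, and the highest other gave 0 (812 at an unadjusted p under 0.05, against 1024). The share was thus under 0.05, but these splits ignore the pairs. The other splits also mix the strains on a side, where a strain difference widens the spread, so their 0 does not exclude chance. The 8 splits that part all numbered pairs, with 287 in the real split against 0 at most in the others, are too few for a share under 0.05. Without both replicate 4 cultures 609 probe sets differed. The larger count does not by itself bear on the source, but 274 of the 287 were among them. That argues against those cultures as the source of most of the calls. Of the higher calls 5.08% (exact 95% interval 2.35 to 9.43%) had a mean signal under 7, against 8.17% of all tested probe sets. Most higher calls were thus not dim by this level, but with so few dim probe sets tested the share could hardly have been large. Without the dimmest 25% of probe sets the calls of at least 2-fold went from 44 higher and 21 lower to 25 and 6. Probe sets left out take their calls with them, so this fall cannot tell whether dim signals are a source. Of the 12 rule-named genes left out, all but zfs1 and isp3 lay above the brightest reporter control on all 8 arrays. Whether dim signals are a source of part of the larger changes stays open. The strain difference had a Spearman rho of -0.027 with gene length across genes. The absence of zfs1 may underlie these changes, but direct and indirect effects were not told apart by any test here.

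The second pattern is the higher core stress list without zfs1. Of the 35 splits 1, the real one, gave a camera p as small (6.00e-08, the smallest other 2.12e-07), and 1 called as many lists (11 against 7 at most). The real split was thus the most extreme, but these splits ignore the pairs. The other splits, some of which keep part of the strain difference, had a median camera p of 0.00765 and a median of 2 lists called. Small camera p-values thus also arose under other groupings, and chance is not excluded. The 8 splits that part all numbered pairs (smallest other 9.15e-07, at most 7 lists in another) are too few for a share under 0.05, and the list had an adjusted p = 0.320 with an estimated correlation. Without the replicate 4 cultures the list's median was 0.41, which argues against them as the source. Cultures further into nutrient limitation might also give this pattern, and that stays open, although the 3 lists examined for it did not meet the bounds set: ribosome biogenesis had a median of -0.10, just short of its bound and on either side of it with 1 array left out (-0.041 to -0.17), ribosomal proteins one of 0.05 and nitrogen starvation genes one of -0.12 (camera adjusted p = 0.412), both on the other side of 0 from their bounds. Of the 119 ribosomal protein probe sets 111 lay in the brightest 5%, and whether small changes are harder to see there was not tested. A response to the loss of zfs1 stays open beside nutrient limitation.

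The third pattern is the replicate 4 cultures, which differed from the others in both strains. Their difference fell with gene length, with a Spearman rho across 2861 genes of -0.42 (-0.37 in wild type and -0.43 in the deficient strain), given without a p because genes are not independent replicates. Genes lower in replicate 4 had a median length of 2692 bases and genes higher a median of 1311. A technical effect that acts by transcript length, such as RNA quality or amplification in a 3′ assay, is a candidate explanation. Cultures further into nutrient limitation might also differ in this way, and that stays open: fbp1 was 2.85 higher (1.41 in wild type and 4.29 in the deficient strain) and the stress list 0.25 in the median, but the lists of ribosome biogenesis (median -0.079), ribosomal proteins (-0.05) and nitrogen starvation genes (-0.25) were not called (camera adjusted p = 0.431 to 0.471) and did not meet the bounds set.

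A single array stood far from the other 3 of its strain in 6 of 94 sets of 4 values, where chance would give about 4.7. The gap, as a share of the range, was 0.937 for lys1 in zfs1-deficient replicate 4 (10.90 against 11.58 to 11.62), 0.841 for mkh1 in the same culture (9.55, the highest of the others 10.09) and 0.956 for gpx1 in the same culture (12.27 against 12.02 to 12.03). It was 0.899 for inv1 in zfs1-deficient replicate 2 (11.38 against 9.79 to 9.95). In wild-type replicate 2 it was 0.872 for gdh2 (10.64 against 9.85 to 9.95) and 0.905 for vtc4 (10.76 against 10.90 to 10.91).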

How the results depend on the processing

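The alternatives with replicate 4 or replicate 2 left out of both strains, replicate 4 as a batch term, the mean of zfs1-deficient replicates 1 and 3, and the offsets were chosen after the data were seen. The zfs1 difference kept its direction and call in all of them and in the planned ones but 1: leaving out the dimmest 25% removed 12 of the 44 genes of the naming rule from the test, zfs1 among them. No gene of that rule changed sign where it was tested. Changed probe sets numbered 287 (177 higher, 110 lower). They were 1517 (761 and 756) with array weights, 1201 (563 and 638) with the replicate block, 103 (74 and 29) with 1 probe set per gene, and 72 (56 and 16) at an adjusted p of 0.01. They were 981 (493 and 488) with replicate 4 as a batch term, 609 (332 and 277) without replicate 4 of both strains, 88 (54 and 34) without replicate 2 of both strains, and 114 (87 and 27) with zfs1-deficient 1 and 3 as 1 sample. With 1 array left out they ranged from 103 to 306 (75 to 184 higher, 28 to 125 lower). At 2-fold, 44 were higher and 21 lower. These became 25 and 6 without the dimmest 25%, 79 and 55 with array weights, 12 and 2 with 1 probe set per gene, 22 and 8 at an adjusted p of 0.01, 32 lower with the block, 26 higher without replicate 2 of both strains, 9 lower with zfs1-deficient 1 and 3 as 1 sample, and 9 lower with the offset of 64. With 1 array left out they ranged from 31 to 47 higher and 9 to 25 lower, with 13 lower without wild-type replicate 1 and 9 without zfs1-deficient replicate 1 or 3. The 1 probe set per gene and stricter counts follow from testing or passing fewer. The lower counts without the dimmest 25% follow at least in part from testing fewer. For the other alternatives the cause was not tested.

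Gene lists called numbered 11, 0 with an estimated correlation (3 at an unadjusted p under 0.05), and 7 to 10 with 1 array left out. The block left all 11 list calls in place, and the calls and counts it moved stand beside the results. Of 36 called genes besides zfs1, 19 kept their call with each single array left out. The AU-rich element search was not run, having no genome, and offsets of 1 and 64 planned for linear values did not apply to log values. Signal over background limits the dim genes: the reporter controls had a median of 3.27 ± 0.20 in wild type and 3.86 ± 0.37 in the deficient strain (SD, n = 4; difference 0.59, 2-sided exact permutation p = 0.0857 with the pairs ignored). They were higher in the deficient strain in 4 of 4 numbered pairs (exact sign-flip p = 0.125, the smallest that 4 pairs can give), and 0 of 12 tested in limma passed (1 at an unadjusted p under 0.05).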

Other observations

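The gene groups here were chosen after the calls were seen, and so were their tests. Of 42 measured genes of amino acid synthesis 0 rose and 8 fell without zfs1, among them arg7 (fell by 0.60), arg5 (fell by 0.51), pro1 (fell by 0.49), trp3 (fell by 0.41) and his5 (fell by 0.37), and 34 had a difference below 0. Their median was -0.16, and 20 fell with the replicate number as a block. Lower levels of this set as a whole may be a feature of the deficient strain: camera gave an adjusted p of 2.94e-06 at the preset correlation, but an adjusted p = 0.458 with an estimated correlation, so the set as a whole cannot be told apart from genes that vary together between cultures. The list was also lower in the replicate 4 cultures (median -0.13, camera adjusted p = 0.0421).

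Genes named mug or meu, from screens for transcripts raised in meiosis, may be over-represented among the increases. Of 106 such genes 7 rose (6.60%), against 80 of 2776 others (2.88%; 2-sided Fisher's exact p = 0.0389), and by the older symbols of the array's annotation 10 of 130 rose (p = 0.00508). They were mug2, mug122, mug182, mug35, mug51, mug174 and meu23. With the replicate number as a block, 12 rose and 10 fell, and the share of increases (11.3%, against 10.3% of the others; 2-sided Fisher's exact p = 0.745) no longer stood out, so the excess holds in 1 of the fits and stays open. The list as a whole was not called by camera (adjusted p = 0.375; adjusted p = 0.458 with an estimated correlation), with a median of 0.10.

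Of 4 trehalose genes 2 rose, tpp1 by 0.86 and tps1 by 0.41 (camera adjusted p = 3.63e-04; adjusted p = 0.102 with an estimated correlation), and 3 rose with the block. The estimated correlation was -0.019, below the preset, so correlation between these genes does not account for the weaker result. Among 44 DNA repair genes 5 rose, mus81 (0.85), uve1 (0.78), nth1 (0.78), rhp14 (0.69) and rhp7 (0.67), and msh3 fell by 0.60, with no call for the list (camera adjusted p = 0.225; adjusted p = 0.516 with an estimated correlation). With the block 8 of these rose and 5 fell.

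The strains' arrays did not overlap for 772 probe sets (15.5%), where chance gives 2.86%. Of the 287 changed probe sets, 284 differed the same way in all 4 numbered pairs. Any probe set without overlap must do so, so this count adds little to the calls. In the replicate 4 cultures, pan1 differed by -1.78 from the others and spo5 by -2.33.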
